A study of Rattus norvegicus with 47 samples.

How the data were processed

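RNA was measured in lung and whole blood libraries of rats exposed to air or silica. Per the labels' protocols, lung RNA was isolated with a kit for fibrous tissue, blood was drawn into K2EDTA and an RNA preservative, globin RNA was depleted from blood RNA, and libraries were stranded and made from polyadenylated RNA. The submitters' processing notes name bcl2fastq 2.19, cutadapt 3.4, Trim Galore 0.6.7, STAR 2.6.1d, Salmon 1.10.1 and the genome build Rnor_6.0, with no role or order given. The deposited tables, 1 for each tissue and time, hold estimated counts per gene, expected counts that need not be whole and are not normalized, with gene names; they were rounded to whole numbers here. Estimated counts split reads between similar genes, so values of gene families, overlapping genes and gene models of the same name are uncertain; 266 gene names stood on more than 1 line of a table. All columns of the 4 tables were matched to samples by their titles, with 0 columns left over. The reference table used for names was that of GRCr8, and no coordinate was taken from it.

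Libraries were grouped by tissue, time and treatment as the labels state. The labels give neither the chambers, the cage pairs nor the time of killing, so p-values measure the spread between animals of a group. Treatment and chamber therefore cannot be told apart, and a silica effect below is a difference between the silica and air groups. Replicates were compared first: the chi-square per degree of freedom between libraries of a group ran from 3.76 to 35.3, so no pair agreed within sampling noise. Total counts ran from 9.64e6 to 25.9e6 per library, and a floor is 3 counts per library, which covers counting error only.

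Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05), silica against air within each table. SE is the size of the log2 fold change over the root of the F statistic. Time and tissue differences were tested as interactions over 4 groups. Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over the lists; "adjusted over the list alone" counts members by Benjamini-Hochberg within the list. The 27 lists hold 515 genes, of which 15 were not found in the tables by the name used: inflammatory chemokines, inflammasome and IL-1 family, neutrophil, macrophage and foam cell, monocyte, complement, NRF2 and oxidative stress, collagen and matrix remodelling, alveolar type 2, alveolar type 1, club and goblet, ciliated, endothelial, fibroblast and smooth muscle, proliferation, interferon-stimulated, MHC class II, T cell, B cell, NK and cytotoxic, mast cell and granulocyte, erythroid, platelet, immediate-early, adipose, muscle and mesothelial, NF-kB and circadian clock genes. Of the genes 3 stand on 2 lists, and lung cells of several types express many of them. The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined; list tests of the interactions, robust dispersion estimates, summed gene models and the fit without 4 blood libraries were added later.

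Named genes were chosen by rule. Among genes past the threshold with a symbol and a mean of at least 5 CPM in the higher group, the 8 largest rises and the 8 largest falls were named. From each list called by camera the 3 members with the smallest p were named. Where fewer than 5 genes passed, the 5 smallest p-values were named. In each time interaction the 5 smallest p-values past the threshold were named, and from each overlap of lung and blood up to 10 shared calls. A few genes that the rule names are not reported here. Ccl2, Cxcl1, Lcn2, Spp1, Slc26a4, Sod2, Hmox1, Sftpc, Scgb1a1 and Col1a1 were always named in lung, and S100a8, S100a9, Csf3r, Alas2, Ms4a1, Cd3e, Lcn2 and Isg15 in blood. Single values per library were compared by two-sided exact permutation tests, overlaps by one-sided Fisher's exact tests beside the number independent lists would share.

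Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, a minimum count of 50, no filter and a test against a 1.5-fold change. Further ones were 1 surrogate variable from sva 3.50.0, all 4 groups of a tissue in 1 model, fry and an estimated correlation. In another, mitochondrial ribosomal RNA, globin and erythroid genes were left out before normalization. Overlaps were also counted at a stricter threshold of 0.01, and each library was left out in turn. Lung and blood titles carry the same animal numbers, taken as the same animal because each title gives 1 number per rat, which the labels do not state outright; the animal was therefore a block in an alternative to the tissue comparisons. After subtracting group means, same-numbered lung and blood libraries correlated across genes from -0.086 to 0.177 at 1 day (3 of 12 above 0.1) and from -0.082 to 0.092 at 6 months (0 of 9). On simulated counts with 200 changed genes, a 1.5-fold change was recovered for 76% of genes with the libraries of lung at 1 day, 64% of lung at 6 months, 76% of blood at 1 day and 64% of blood at 6 months, and a list changed 1.5-fold was called in all 8 comparisons with 0 of 20 unchanged lists called by camera. Each gene was simulated independently of the others, so the simulation could not show list calls that arise from correlation between genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.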

Results

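RNA was sequenced from lung tissue and whole blood of healthy male Fischer 344 rats, an inbred laboratory strain. The rats had breathed filtered air or airborne Min-U-Sil 5, a fine crystalline silica dust, in whole-body chambers at 15 mg/m3 for 6 h a day on 5 days. They were killed 1 day or 6 months after exposure, which gave 8 groups of tissue, time and treatment. Each group held 6 libraries of separate animals except air lung at 6 months, which held 5, for 47 libraries in all. Total estimated counts, in units of 1e6, ranged in lung over 12.1 to 25.9 (air) and 13 to 16.7 (silica) at 1 day. At 6 months they ranged over 12.1 to 13.6 and 12.8 to 19.8. In blood they ranged over 12.9 to 16.9 (air) and 12.0 to 18.3 (silica) at 1 day, and over 11.4 to 19.3 and 9.64 to 13.5 at 6 months. Each table of counts listed 30045 genes and held 1 tissue at 1 time, so the air groups of different times were not compared with each other. Gene values are log2 fold changes of silica over air ± SE unless another unit is given, with n as above and p adjusted by edgeR.

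Globin transcripts in lung can come from red cells in its vessels, a source that was not tested. They took 0.533% ± 0.0589 of counts in air lung and 0.390% ± 0.0373 in silica lung at 1 day (SD, n = 6 each; exact permutation p = 0.00433). That p was 0.0693 adjusted over 16 such tests. At 6 months the shares were 0.63% and 0.474% (n = 5 and 6; exact permutation p = 0.0238, adjusted 0.110). Mean total counts at 6 months were 12641100 in air and 16417900 in silica lung (exact permutation p = 0.0260). In blood they were 15228500 and 11724200 (exact permutation p = 0.0390), with an adjusted p of 0.110 for each. None of the 16 tests passed the correction. Summed CPM of 3 heart muscle genes reached 387 in a library of air lung at 6 months. Summed CPM of 4 liver genes reached 25.6 in a library of air blood at 1 day.

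The lung at 1 day was compared to ask which transcripts differed soon after inhaled silica. Chemokines that draw in neutrophils rose: Cxcl6 (log2 4.30 ± 0.25, adjusted p = 3.85e-07), Cxcl2 (log2 2.71 ± 0.22) and Cxcl1 (log2 2.59 ± 0.24). The monocyte chemokines Ccl2 (6.08-fold, adjusted p = 6.76e-07) and Ccl7 (6.06-fold, adjusted p = 1.48e-06) rose as well. Lcn2, which encodes the iron-sequestering protein lipocalin 2, went from 5.47 ± 1.36 CPM in air to 46.0 ± 10.2 CPM in silica lung (SD, n = 6 each; log2 3.05 ± 0.18, adjusted p = 3.85e-07). Slc26a4, the anion exchanger pendrin, went from 10.7 ± 5.30 to 57.7 ± 10.3 CPM (log2 2.44 ± 0.24, adjusted p = 1.37e-05). All 6 silica lungs lay above all 6 air lungs for Lcn2, Ccl2, Cxcl6 and Slc26a4. Sod2, the mitochondrial superoxide dismutase, rose (2.65-fold, adjusted p = 3.85e-07), as did Hmox1, heme oxygenase 1 (log2 0.54 ± 0.10). Scgb1a1, the main secretory protein of club cells, fell (log2 -0.37 ± 0.092, adjusted p = 0.0140). Spp1 (log2 0.43 ± 0.24, adjusted p = 0.266), Sftpc (log2 0.07 ± 0.055, adjusted p = 0.476) and Col1a1 (log2 -0.0090 ± 0.075, adjusted p = 0.959) did not pass the test.

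At 1 day 14 of 27 gene lists passed the test in lung, 9 of them upward. Of 21 inflammatory chemokines 14 rose and 2 fell (14 and 3 adjusted over the list alone). The chemokine median was log2 0.69 (camera adjusted p = 4.13e-22, adjusted p = 0.00483 with an estimated correlation). The 2 that fell were Ccl24 and Cxcl9, named after their values were seen. Of 28 cell proliferation genes 27 rose and 0 fell (27 and 0 adjusted over the list alone). The proliferation median was log2 1.12 (camera adjusted p = 2.93e-55, adjusted p = 0.00176 with an estimated correlation). They were led by Cenpf (log2 1.14 ± 0.078), Mki67 (2.61-fold, adjusted p = 1.96e-06) and Tk1 (1.99-fold, adjusted p = 3.45e-06), genes of chromosome segregation, cycling cells and nucleotide supply. Of 16 inflammasome and IL-1 family genes 8 rose and 1 fell (9 and 2 adjusted over the list alone). The inflammasome median was log2 0.25 (camera adjusted p = 4.53e-05, adjusted p = 0.0136 with an estimated correlation). Those that rose included the decoy receptor Il1r2 (log2 2.44 ± 0.26), the sensor Nlrp3 (log2 0.55 ± 0.067) and the antagonist Il1rn (log2 0.55 ± 0.069).

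Of 20 neutrophil markers 11 rose and 3 fell (11 and 3 adjusted over the list alone). The neutrophil median was log2 0.50 (camera adjusted p = 4.33e-07, adjusted p = 0.0489 with an estimated correlation). Trem1 (log2 0.65 ± 0.083) and Ncf4 (log2 0.50 ± 0.061) rose, while of 2 similar receptors for such chemokines Cxcr1 fell (log2 -1.04 ± 0.19) and Cxcr2 rose (log2 1.14 ± 0.21), with reads that can be hard to tell apart. Of 16 complement genes 9 rose and 1 fell (11 and 2 adjusted over the list alone). The complement median was log2 0.26 (camera adjusted p = 7.75e-09, adjusted p = 0.0489 with an estimated correlation). C3 (log2 1.69 ± 0.10) and C1s (log2 0.47 ± 0.053) rose and Cfd, which adipocytes also express, fell (log2 -0.70 ± 0.093). Of 19 genes of NF-kB and acute inflammatory signalling 9 rose and 0 fell (14 and 0 adjusted over the list alone). The NF-kB median was log2 0.41 (camera adjusted p = 3.20e-07, adjusted p = 0.0489 with an estimated correlation). Among them were the growth factor gene Csf1 (log2 0.57 ± 0.061), Nfkbiz (log2 0.87 ± 0.11) and E-selectin, Sele (2.6-fold, adjusted p = 6.56e-04).

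Alveolar type 1, endothelial and fibroblast lists tested lower at 1 day. Of 11 markers of alveolar type 1 cells, which form most of the gas exchange surface, 0 rose and 5 fell (0 and 8 adjusted over the list alone). The alveolar type 1 median was log2 -0.12 (camera adjusted p = 9.36e-05, adjusted p = 0.0122 with an estimated correlation). Cav1 (log2 -0.27 ± 0.033), Hopx (log2 -0.28 ± 0.045) and Ager (log2 -0.20 ± 0.054) fell. The Ager call was lost without air 42 (adjusted p = 0.0516) or silica 48 (adjusted p = 0.0524). Of 13 endothelial markers 0 rose and 7 fell (0 and 9 adjusted over the list alone). The endothelial median was log2 -0.17 (camera adjusted p = 7.07e-06, adjusted p = 0.0975 with an estimated correlation). The endothelin receptor Ednrb (log2 -0.20 ± 0.031), the junction gene Cldn5 (log2 -0.35 ± 0.083) and Pecam1 (log2 -0.19 ± 0.047) fell. Of 12 fibroblast and smooth muscle markers 0 rose and 2 fell (0 and 5 adjusted over the list alone). The fibroblast median was log2 -0.15 (camera adjusted p = 0.00222, adjusted p = 0.316 with an estimated correlation). Pdgfrb (log2 -0.16 ± 0.040) and Lum (log2 -0.41 ± 0.11) fell, while Tcf21 missed the threshold (log2 -0.18 ± 0.058, adjusted p = 0.0516).

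The globin share was lower in the same silica lungs. Of 16 erythroid genes 1 rose and 7 fell (3 and 9 adjusted over the list alone). The erythroid median was log2 -0.24 (camera adjusted p = 0.0278, adjusted p = 0.316 with an estimated correlation). Hbb (log2 -0.47 ± 0.078) and Hba1 (log2 -0.44 ± 0.074), both globins, fell, and the transferrin receptor Tfrc rose (log2 0.60 ± 0.066). Of 26 interferon-stimulated genes 4 rose and 0 fell (4 and 0 adjusted over the list alone). The interferon median was log2 0.10 (camera adjusted p = 0.0115, adjusted p = 0.682 with an estimated correlation). Ifit3 (log2 0.67 ± 0.12), Ifit1 (log2 1.32 ± 0.27) and Isg15 (log2 0.28 ± 0.074) rose. Without silica 46 the calls of the erythroid list (adjusted p = 0.0636) and the interferon list (adjusted p = 0.0846) were lost. Of 14 genes of MHC class II antigen presentation 4 rose and 0 fell (7 and 0 adjusted over the list alone). The MHC class II median was log2 0.19 (camera adjusted p = 0.00186, adjusted p = 0.316 with an estimated correlation). RT1-Bb (log2 0.20 ± 0.039), RT1-Ba (log2 0.19 ± 0.047) and the invariant chain Cd74 (log2 0.17 ± 0.045) rose. The Cd74 call was lost without any 1 of air 40, 41 and 42 and silica 44 and 45 (adjusted p 0.0502 to 0.0642).

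Of 24 macrophage and foam cell genes 7 rose and 4 fell (9 and 5 adjusted over the list alone). The macrophage median was log2 0.07 (camera adjusted p = 0.0115, adjusted p = 0.682 with an estimated correlation). In front were Chi3l1, a secreted chitinase-like protein (log2 1.58 ± 0.10), the integrin Itgax (log2 0.55 ± 0.066) and the proton pump subunit Atp6v0d2 (2.15-fold, adjusted p = 6.17e-04). The NK and cytotoxic list tested lower with 0 of 15 members past edgeR's threshold, also 0 adjusted over the list alone. The NK median was log2 -0.27 (camera adjusted p = 0.00695, adjusted p = 0.656 with an estimated correlation). Gzma (log2 -0.28 ± 0.095, adjusted p = 0.0608), Klrb1a (log2 -0.38 ± 0.13, adjusted p = 0.0615) and Klrg1 (log2 -0.43 ± 0.16, adjusted p = 0.0803) had its smallest p-values. Of the 14 list calls at 1 day 7 held with an estimated correlation, and fry, which does not compare a list with other genes, called 11 of the 27.

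Among the largest single changes at 1 day, Ly6al (log2 3.45 ± 0.32), C2cd4b (log2 2.71 ± 0.23) and Saal1 (log2 3.06 ± 0.24) rose. The reference table gives Saal1 both as its own gene and as another name of the acute-phase gene Saa3, so its identity was left open. Dlk1, a Notch pathway ligand (log2 -2.26 ± 0.28), the hair-follicle protein gene Tchh (log2 -1.24 ± 0.17) and Tnfrsf8, which encodes CD30 (log2 -1.21 ± 0.17), fell. The lipoxygenase Alox15 (log2 -1.11 ± 0.089) and the sulfatase Arsi (log2 -1.11 ± 0.13) fell too. In all, 2163 of 15331 genes passed edgeR's test, 1286 higher and 877 lower, of which 204 and 15 changed at least 2-fold.

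Rfxap, a subunit of the factor that drives MHC class II genes, was estimated at 0 counts in all 6 silica lungs at 1 day and at 154 to 406 counts in air lungs. That was at least 69.2-fold lower against a floor of 3 counts per library. A second gene model of the name Rfxap held 267 to 348 counts in silica and 33 to 171 in air lungs. The sum of both did not pass the test (log2 -0.019 ± 0.060, adjusted p = 0.882). Lilra3 was estimated at 0 to 7 counts in air and 25 to 171 in silica lungs (adjusted p = 1.26e-04). Slc25a22 was estimated at 0 to 411 counts in air and 0 to 33 in silica lungs (adjusted p = 0.0435). Slc25a22 switched between 0 and high values within groups, as did Lilra3 in lung at 6 months. The Slc25a22 call was lost without each of 10 of the 12 libraries (adjusted p 0.0527 to 0.0936). DESeq2 (adjusted p = 0.180), limma-voom (0.602) and 1 surrogate variable (0.0513) lost it too. So did all 4 lung groups in 1 fit (0.0610) and robust dispersion estimates (0.0991).

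**Figure D1:**
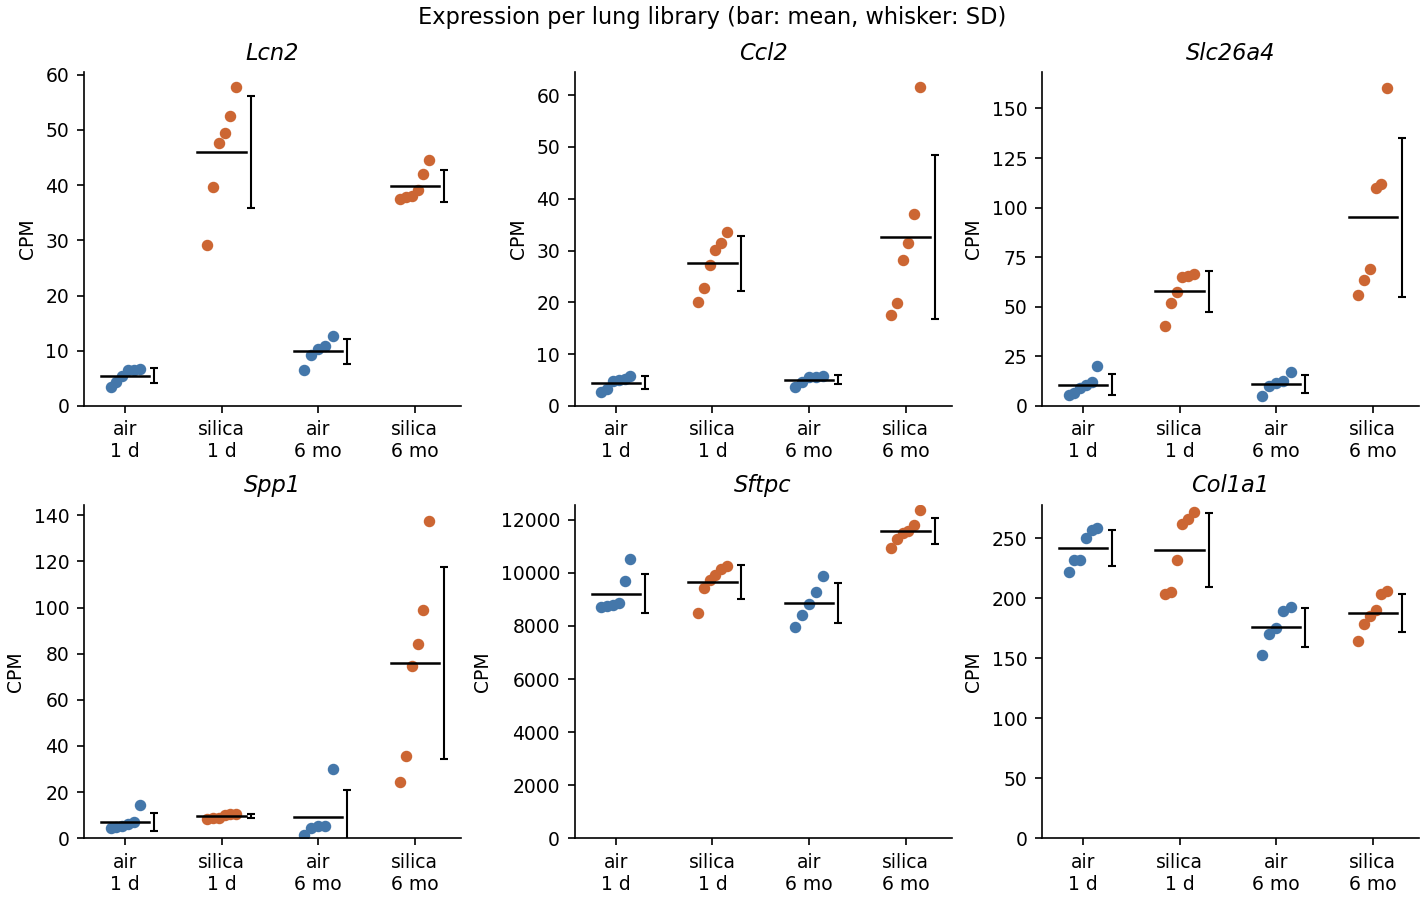
CPM of Lcn2, Ccl2, Slc26a4, Spp1, Sftpc and Col1a1 in each lung library, by time and treatment (6 libraries per group, 5 in air at 6 months), with each point 1 library, the bar the mean and the whisker the SD, which for Spp1 in air lung at 6 months extends below 0 and ends at the axis. Lcn2, Ccl2 and Slc26a4 were higher in silica lung at both times, Spp1 and Sftpc at 6 months.

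At 6 months the comparison asked what persisted in the lung long after exposure. Lists of macrophage genes and of alveolar type 2 cells, which make surfactant, tested higher, calls lost with an estimated correlation (adjusted p = 0.0772 each). Spp1, which encodes osteopontin, went from 9.21 ± 11.7 CPM in air (SD, n = 5) to 75.9 ± 41.7 CPM in silica lung (SD, n = 6; log2 3.06 ± 0.62, adjusted p = 0.00565), with air 54 alone at 29.9 CPM. Sftpc, surfactant protein C, went from 8867 ± 759 to 11581 ± 488 CPM (log2 0.39 ± 0.054, adjusted p = 6.31e-04). Lpo, lactoperoxidase (log2 4.20 ± 0.69), the resistin-like gene Retnla (log2 3.59 ± 0.49), the airway secretory gene Bpifb1 (log2 3.13 ± 0.51) and Slc26a4 (log2 3.10 ± 0.33, adjusted p = 1.16e-04) had the largest rises. Ccl7 (log2 3.02 ± 0.49), Cxcl6 (log2 2.91 ± 0.22) and Ccl2 (log2 2.69 ± 0.32) followed. Lpo was at 2.08 ± 4.08 CPM in air (SD, n = 5) and 37.6 ± 13.2 CPM in silica lung (SD, n = 6). The size of its fold change thus rests on low and uneven air values. Lcn2 went from 9.88 ± 2.29 to 39.8 ± 2.87 CPM (log2 2.01 ± 0.12, adjusted p = 8.88e-06). Cxcl1 (log2 1.03 ± 0.10), Sod2 (log2 1.04 ± 0.077) and Hmox1 (log2 1.06 ± 0.12) rose. Scgb1a1 (log2 -0.20 ± 0.10, adjusted p = 0.214) and Col1a1 (log2 0.09 ± 0.069, adjusted p = 0.386) did not pass the test.

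Of 24 macrophage and foam cell genes 22 rose and 1 fell (22 and 1 adjusted over the list alone). The macrophage median was log2 0.62 (camera adjusted p = 2.14e-31, adjusted p = 0.0772 with an estimated correlation). They were led by Chi3l1 (log2 1.19 ± 0.089), Atp6v0d2 (2.6-fold, adjusted p = 1.62e-05) and Itgax (log2 0.84 ± 0.10). Of 14 surfactant and alveolar type 2 genes 11 rose and 0 fell (13 and 0 adjusted over the list alone). The alveolar type 2 median was log2 0.43 (camera adjusted p = 3.13e-16, adjusted p = 0.0772 with an estimated correlation). The phospholipid acyltransferase Lpcat1 (log2 0.63 ± 0.078), the lamellar body transporter Abca3 (log2 0.32 ± 0.041) and the protease Napsa (log2 0.48 ± 0.065) rose. Of 28 proliferation genes 24 rose and 0 fell (26 and 0 adjusted over the list alone). The proliferation median was log2 0.78 (camera adjusted p = 8.65e-20, adjusted p = 0.0772 with an estimated correlation). Rrm2 (log2 1.23 ± 0.11), Cdk1 (log2 0.89 ± 0.10) and Bub1b (log2 1.33 ± 0.16), which serve DNA synthesis and mitosis, were in front.

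Of 21 inflammatory chemokines 12 rose and 0 fell (15 and 2 adjusted over the list alone). The chemokine median was log2 0.81 (camera adjusted p = 8.71e-14, adjusted p = 0.0772 with an estimated correlation). The neutrophil chemokine Cxcl3 (log2 0.56 ± 0.047) was among those that rose. Of 16 complement genes 10 rose and 0 fell (11 and 0 adjusted over the list alone). The complement median was log2 0.41 (camera adjusted p = 3.04e-14, adjusted p = 0.0772 with an estimated correlation). C3 (log2 1.19 ± 0.084), Cfb (log2 0.83 ± 0.10) and C1qa (log2 0.49 ± 0.058) rose. Of 21 neutrophil markers 8 rose and 0 fell (8 and 1 adjusted over the list alone). The neutrophil median was log2 0.09 (camera adjusted p = 2.31e-07, adjusted p = 0.0980 with an estimated correlation). The calprotectin subunit S100a9 rose (log2 1.51 ± 0.14).

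Of 22 genes of the NRF2 and oxidative stress response 8 rose and 2 fell (10 and 2 adjusted over the list alone). The NRF2 median was log2 0.14 (camera adjusted p = 3.82e-07, adjusted p = 0.0982 with an estimated correlation). Srxn1, sulfiredoxin, rose (log2 1.24 ± 0.13). Of 14 MHC class II genes 7 rose and 0 fell (7 and 0 adjusted over the list alone). The MHC class II median was log2 0.31 (camera adjusted p = 1.05e-05, adjusted p = 0.121 with an estimated correlation). RT1-Da (log2 0.37 ± 0.052), RT1-Bb (log2 0.43 ± 0.064) and RT1-Db1 (log2 0.35 ± 0.071), chains of the antigen-presenting molecules, rose.

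The same 3 lists tested lower at 6 months, and all 3 calls were lost with an estimated correlation. Of 13 endothelial markers 0 rose and 12 fell (0 and 12 adjusted over the list alone). The endothelial median was log2 -0.23 (camera adjusted p = 1.29e-10, adjusted p = 0.0772 with an estimated correlation). The receptor Tek (log2 -0.34 ± 0.055), Pecam1 (log2 -0.26 ± 0.042) and Esam (log2 -0.19 ± 0.036) fell. Of 12 fibroblast and smooth muscle markers 0 rose and 3 fell (0 and 9 adjusted over the list alone). The fibroblast median was log2 -0.26 (camera adjusted p = 3.14e-05, adjusted p = 0.0772 with an estimated correlation). Inmt (log2 -0.38 ± 0.077), Lum (log2 -0.40 ± 0.10) and decorin, Dcn (log2 -0.53 ± 0.13), fell. Of 11 alveolar type 1 markers 1 rose and 3 fell (1 and 4 adjusted over the list alone). The alveolar type 1 median was log2 -0.14 (camera adjusted p = 0.0143, adjusted p = 0.488 with an estimated correlation). Clic5 (log2 -0.17 ± 0.040) and Cav1 (log2 -0.26 ± 0.064) fell and Cldn18 rose (log2 0.15 ± 0.038). The Clic5 call was lost with no filter (adjusted p = 0.0579). Without air 52 the alveolar type 1 call was lost (adjusted p = 0.0621).

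Ciliated cell markers tested lower with only the tubulin-binding gene Tppp3 of 11 past the threshold (log2 -0.26 ± 0.071, adjusted p = 0.0255), 2 adjusted over the list alone. The ciliated median was log2 -0.25 (camera adjusted p = 0.00275, adjusted p = 0.497 with an estimated correlation). Dynlrb2 (log2 -0.44 ± 0.14) and Tekt1 (log2 -0.39 ± 0.14) missed the threshold. Tppp3 was lost without air 49 (adjusted p = 0.0608), 51 (0.0608) or 52 (0.0582). The NK and cytotoxic list had granzyme B, Gzmb, as the only 1 of 15 called (log2 -0.71 ± 0.21, adjusted p = 0.0345), 5 adjusted over the list alone. The NK median was log2 -0.42 (camera adjusted p = 2.05e-04, adjusted p = 0.488 with an estimated correlation). Tbx21 (log2 -0.42 ± 0.14, adjusted p = 0.0531) and Gzma (log2 -0.49 ± 0.16, adjusted p = 0.0548) were not called. Gzmb was lost without each of air 51, 52 and 54 and silica 59, 60, 61 and 62 (adjusted p 0.0521 to 0.0835).

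Of 19 immediate-early genes, which respond within minutes to stimuli, 1 rose and 1 fell (1 and 0 adjusted over the list alone). The immediate-early median was log2 -0.34 (camera adjusted p = 0.0253, adjusted p = 0.621 with an estimated correlation). Egr2 rose (log2 0.67 ± 0.13), Cyr61 fell (log2 -0.64 ± 0.20, adjusted p = 0.0473) and Zfp36 was not called (log2 -0.44 ± 0.17, adjusted p = 0.0981). That list call was lost without air 49 (adjusted p = 0.129), 52 (0.132) or 54 (0.0646) or silica 59 (0.0797), 61 (0.0854) or 64 (0.0828). Cyr61 was lost without 8 of the 11 libraries (adjusted p 0.0519 to 0.115).

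Of the remaining named falls at 6 months, Dlk1 was the largest (log2 -2.49 ± 0.36), followed by the granzyme-like gene Gzmbl3 (log2 -0.87 ± 0.27, adjusted p = 0.0467) and the calcium-binding protein gene Tesc (log2 -0.77 ± 0.11). Moap1 (log2 -0.76 ± 0.19) and Ddc, which encodes aromatic amino acid decarboxylase (log2 -0.64 ± 0.12), also fell. Reads of Gzmbl3 and Gzmb can be hard to tell apart, and the Gzmbl3 call was lost without each of 9 of the 11 libraries (adjusted p 0.0572 to 0.113). The Moap1 call was lost with all 4 lung groups in 1 fit (adjusted p = 0.103). In all, 2484 of 15309 genes passed edgeR's test, 1507 higher and 977 lower, of which 158 and 9 changed at least 2-fold. All 14 list calls, 8 up and 6 down, were lost with an estimated correlation, whereas fry called 11 of the 27.

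**Figure D2:**
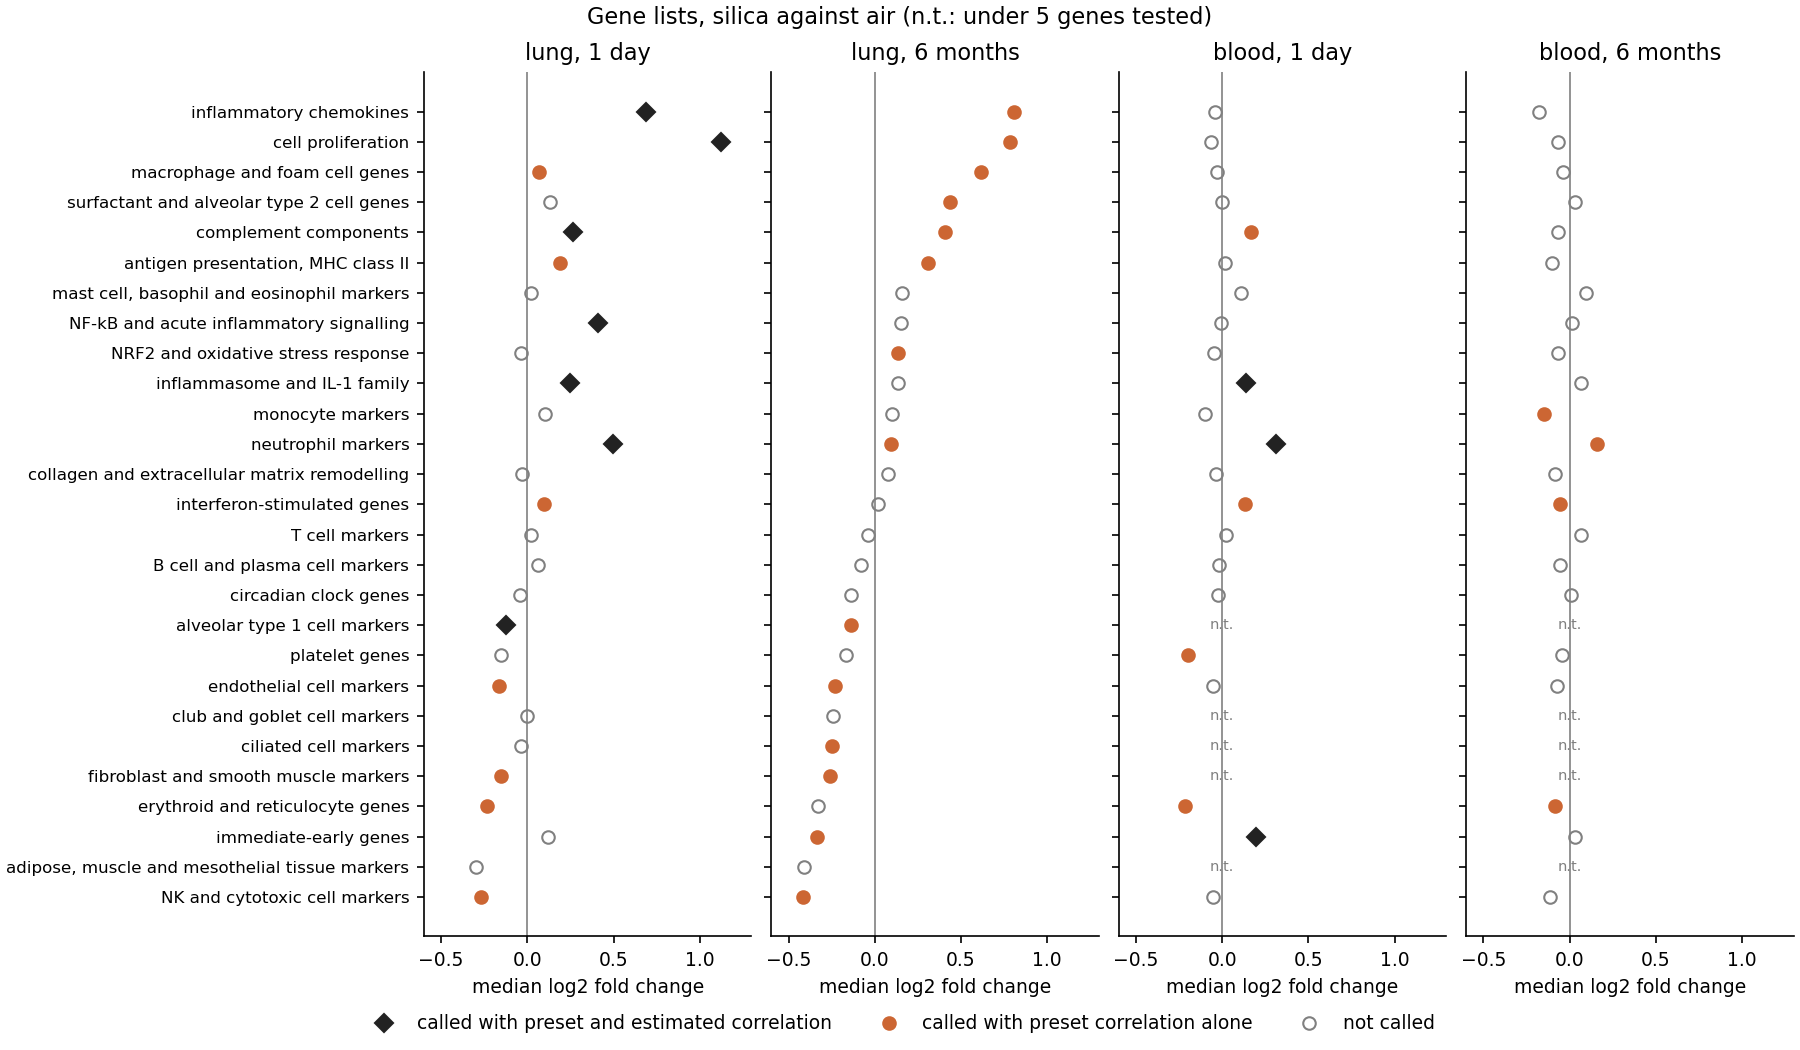
Median log2 fold change, silica over air, of each gene list in lung and blood at each time, with diamonds for lists called with the preset and the estimated correlation, filled circles for the preset alone, open circles for lists not called, and n.t. for lists with fewer than 5 tested genes. Chemokine and proliferation lists lay high in lung at both times, and no list in lung at 6 months carries a diamond.

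Some lung genes moved in opposite directions at the 2 times. The lipid carrier Fabp4 was lower at 1 day and higher at 6 months (log2 -0.82 at 1 day and 1.27 at 6 months, difference 2.09 ± 0.27, adjusted p = 2.86e-04). The same held for Tchh (log2 -1.24 at 1 day and 0.73 at 6 months, difference 1.97 ± 0.19, adjusted p = 4.40e-06) and the oxidase subunit Ncf1 (log2 -0.43 at 1 day and 0.56 at 6 months, difference 0.99 ± 0.12, adjusted p = 1.68e-04). It also held for the keratin Krt79 (log2 -0.96 at 1 day and 0.59 at 6 months, difference 1.55 ± 0.19, adjusted p = 1.68e-04) and Pcsk1n, a proprotein convertase inhibitor (log2 -0.55 at 1 day and 0.74 at 6 months, difference 1.3 ± 0.15, adjusted p = 1.19e-04). Lcn2 (difference -1.03 ± 0.24, adjusted p = 0.0241) and Cxcl1 (difference -1.55 ± 0.29, adjusted p = 0.00621) rose less over air at 6 months than at 1 day. Lcn2 was at 46.0 CPM at 1 day and 39.8 CPM at 6 months in silica lung, and at 5.47 and 9.88 CPM in air lung. Cxcl1 was at 81.4 and 49.6 CPM in silica and 13.2 and 24.2 CPM in air lung. These 2 differences thus also depend on the air groups, which were not compared between times. The surfactant gene Sftpc had a more positive effect at 6 months (difference 0.32, adjusted p = 0.0378). The differences for Spp1 (log2 2.62 ± 0.73, adjusted p = 0.0763), Ccl2 (log2 0.10 ± 0.37, adjusted p = 0.943) and Hmox1 (log2 0.53 ± 0.16, adjusted p = 0.108) did not pass. In all, 217 of 15786 genes had a silica effect that differed between times, 177 more positive and 40 more negative at 6 months.

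List tests of the difference between times were added after the data were seen. Macrophage genes had a more positive effect at 6 months in 5 of 24 members (17 higher and 1 lower adjusted over the list alone). The macrophage median was log2 0.35 (camera adjusted p = 2.09e-20, adjusted p = 0.154 with an estimated correlation). NRF2 genes had a more positive effect in 4 of 22 (10 and 2 lower adjusted over the list alone). The NRF2 median was log2 0.16 (camera adjusted p = 1.82e-07, adjusted p = 0.154 with an estimated correlation). Surfactant and alveolar type 2 genes did so in 3 of 14 (11 adjusted over the list alone). The alveolar type 2 median was log2 0.35 (camera adjusted p = 3.61e-12, adjusted p = 0.186 with an estimated correlation). Proliferation genes had a more negative effect, with 1 of 28 called (10 adjusted over the list alone). The proliferation median was log2 -0.28 (camera adjusted p = 3.57e-08, adjusted p = 0.227 with an estimated correlation). NF-kB genes did too, with 0 of 19 past edgeR's threshold (3 adjusted over the list alone). The NF-kB median was log2 -0.27 (camera adjusted p = 1.56e-04, adjusted p = 0.253 with an estimated correlation).

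Among 15154 genes tested at both times, 702 were higher at both where independent lists would share 125 (one-sided Fisher's exact p at most 1e-300). Another 316 were lower at both where 56.2 would be shared (one-sided Fisher's exact p = 2.29e-165). Called genes with opposite signs numbered 25. The animals of the 2 times were different, so no library entered both comparisons, and genes are not independent of each other.

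**Figure D3:**
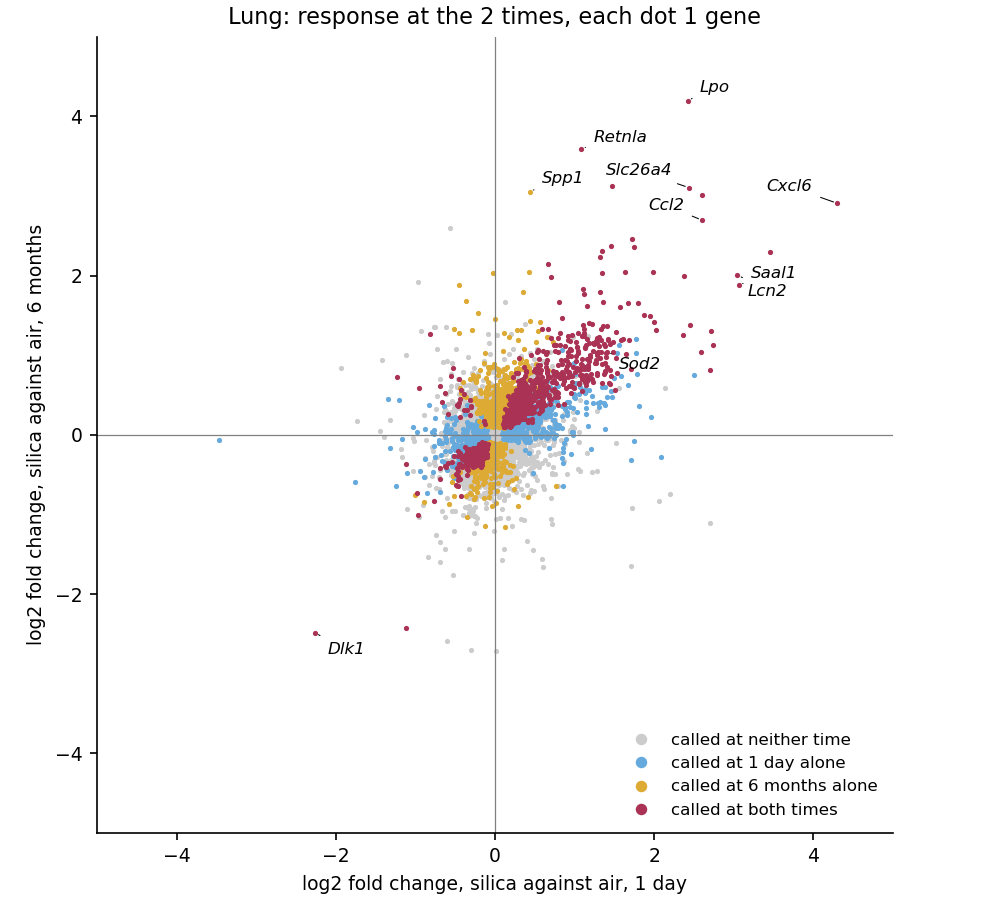
Log2 fold change of silica over air in lung at 1 day (horizontal) and 6 months (vertical) for 15152 genes tested at both times, with 2 genes outside the plotted range of 5. Cxcl6, Lcn2, Ccl2, Slc26a4 and Lpo lie far above 0 on both axes, Retnla and Spp1 farther on the vertical one, and Dlk1 far below 0 on both.

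The blood comparisons asked whether silica inhaled into the lung left a trace in circulating cells. At 1 day neutrophil genes were higher in silica blood. S100a8, a subunit of calprotectin, went from 530 ± 38.0 to 899 ± 65.1 CPM (SD, n = 6 each; log2 0.76 ± 0.065, adjusted p = 1.33e-04). S100a9, the other subunit, went from 1295 ± 109 to 2206 ± 178 CPM (log2 0.77 ± 0.074, adjusted p = 3.00e-04). The antimicrobial protein gene Pglyrp1 (log2 0.73 ± 0.075), the collagenase Mmp8 (log2 0.71 ± 0.089), the Fc receptor Fcar (log2 0.63 ± 0.086) and Padi4, the citrullinating enzyme of neutrophils (log2 0.61 ± 0.068), also rose. Among the largest falls was Itga4, an integrin subunit of lymphocytes and monocytes (log2 -0.37 ± 0.067). The growth factor receptor Csf3r (log2 0.31 ± 0.078, adjusted p = 0.0678), Isg15 (log2 0.48 ± 0.13, adjusted p = 0.0975) and the erythroid heme gene Alas2 (log2 -0.22 ± 0.11, adjusted p = 0.423) did not pass. Nor did the B cell gene Ms4a1 (log2 0.05 ± 0.14, adjusted p = 0.916) or the T cell gene Cd3e (log2 0.02 ± 0.074, adjusted p = 0.957). Lcn2 had too few counts in blood to be tested at either time.

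Of 19 neutrophil markers in blood 7 rose and 0 fell (13 and 0 adjusted over the list alone). The neutrophil median was log2 0.31 (camera adjusted p = 1.70e-29, adjusted p = 4.34e-04 with an estimated correlation). The list score of all 6 silica libraries lay above that of all 6 air libraries. Of 15 inflammasome and IL-1 family genes 4 rose and 0 fell (5 and 0 adjusted over the list alone). The inflammasome median was log2 0.14 (camera adjusted p = 2.12e-06, adjusted p = 0.0197 with an estimated correlation). Il1r2 (log2 0.63 ± 0.11), Il1rn (log2 0.33 ± 0.064) and Nlrp3 (log2 0.33 ± 0.065) rose. Of 17 immediate-early genes 1 rose and 0 fell (4 and 0 adjusted over the list alone). The immediate-early median was log2 0.19 (camera adjusted p = 3.88e-05, adjusted p = 0.0197 with an estimated correlation). The phosphatase Dusp1 was the 1 that rose (log2 0.43 ± 0.074), with Junb (log2 0.24 ± 0.068, adjusted p = 0.119) and Zfp36 (log2 0.19 ± 0.059, adjusted p = 0.147) not called.

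Of 10 complement genes in blood 2 rose and 0 fell (3 and 0 adjusted over the list alone). The complement median was log2 0.17 (camera adjusted p = 0.00662, adjusted p = 0.588 with an estimated correlation). Cfd (log2 0.42 ± 0.088) and the receptor C5ar1 (log2 0.27 ± 0.059) rose and C4b was not called (log2 0.37 ± 0.12, adjusted p = 0.200). The complement call was lost without air 42 (adjusted p = 0.0549) or silica 46 (0.0824). Of 26 interferon-stimulated genes in blood 2 rose and 0 fell (6 and 0 adjusted over the list alone). The interferon median was log2 0.13 (camera adjusted p = 2.12e-06, adjusted p = 0.760 with an estimated correlation). Ifit1 (log2 0.47 ± 0.10) and Ifit3 (log2 0.54 ± 0.12) rose and Ifit2 was not called (log2 0.50 ± 0.13, adjusted p = 0.0839).

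Erythroid and platelet lists tested lower in blood at 1 day with 0 of 25 and 0 of 16 members past edgeR's threshold, also 0 adjusted over the list alone. The erythroid median was log2 -0.22 (camera adjusted p = 3.04e-06, adjusted p = 0.760 with an estimated correlation). Its leading members were Slc4a1 (log2 -0.41 ± 0.12, adjusted p = 0.147), Ank1 (log2 -0.34 ± 0.11) and Slc25a37 (log2 -0.37 ± 0.13), of the red cell membrane and iron import. The platelet median was log2 -0.20 (camera adjusted p = 0.00662, adjusted p = 0.920 with an estimated correlation). Its leading members were Itgb3 (log2 -0.42 ± 0.15, adjusted p = 0.218), Gp1ba (log2 -0.31 ± 0.15) and Tubb1 (log2 -0.32 ± 0.18), which serve platelet adhesion and shape. Liver transcripts stood out in air 37 and 40 and silica 43 and 46, at 11.3, 25.6, 21.7 and 12.9 CPM. Without these 4 libraries the erythroid median was -0.07 (adjusted p = 0.776) and the platelet median 0.02 (adjusted p = 0.529). The platelet call was also lost without air 40 (adjusted p = 0.0554) or 41 (0.121) or silica 43 (0.374) or 46 (0.0709).

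In all, 168 of 12253 genes passed edgeR's test in blood at 1 day, 146 higher and 22 lower, and DESeq2 called 353, 271 higher and 82 lower. The other named rises were Mycbpap (log2 0.77 ± 0.16) and the cystatin-like gene Stfa2l3 (log2 0.71 ± 0.15). Named falls were Ikzf3, a lymphocyte transcription factor (log2 -0.40 ± 0.078), the coactivator Ncoa2 (log2 -0.36 ± 0.077), the transporter Abcc1 (log2 -0.36 ± 0.082) and Ankrd52 (log2 -0.42 ± 0.081). Adck5 (log2 -0.40 ± 0.091), the interferon-inducible Gvinp1 (log2 -0.77 ± 0.18) and Mycbp2 (log2 -0.82 ± 0.17) fell too. For Mycbp2 the sum of the gene models of that name did not pass (log2 -0.18, adjusted p = 0.328).

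The count of 168 fell to 95 without air 37, 92 without air 38, 90 without air 41 and 95 without air 42. It fell to 86 without silica 45, 90 without silica 46, 87 without silica 48, and 74 without the 4 libraries with liver transcripts. The calls of S100a8, S100a9, Pglyrp1, Padi4, Mmp8, Fcar, Dusp1, Il1r2 and Itga4 held whichever single library was left out. Without those 4 libraries Dusp1 (adjusted p = 0.0531) and Itga4 (0.149) were lost. In that fit, on fewer samples, Nlrp3 (adjusted p = 0.0592), Il1rn (0.0604), Ifit1 (0.0700), Stfa2l3 (0.0799), Adck5 (0.103) and Abcc1 (0.107) were lost too. So were Mycbp2 (adjusted p = 0.113), Cfd (0.114), C5ar1 (0.183) and Ncoa2 (0.214). Dusp1 was also lost with all 4 blood groups in 1 fit (adjusted p = 0.0824). Ankrd52 was lost without silica 45 (adjusted p = 0.0522), and Il1rn without air 42 (0.0552) or silica 45 (0.0514) or 48 (0.0599). Nlrp3 was lost without air 38 (adjusted p = 0.0575) or 42 (0.0562) or silica 45 (0.0618), 46 (0.0609) or 48 (0.0639). Cfd, Ifit1 and Mycbpap were lost without 7 of the 12 libraries each (adjusted p 0.0503 to 0.0843), and Ikzf3, Mycbp2, Ncoa2 and Stfa2l3 without 8 (0.0507 to 0.0930). C5ar1, Ifit3, Adck5, Abcc1 and Gvinp1 were lost without 9 to 11 (adjusted p 0.0503 to 0.117).

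At 6 months the neutrophil list was slightly higher in silica blood and the monocyte, interferon-stimulated and erythroid lists lower, with 0 members past edgeR's threshold. The neutrophil median was log2 0.16 (camera adjusted p = 0.0172, adjusted p = 0.843 with an estimated correlation). Cxcr2 (log2 0.30 ± 0.12, adjusted p = 0.539), Mmp8 (log2 0.31 ± 0.12) and, in the other direction, Ngp (log2 -0.43 ± 0.16), all of granules or chemotaxis, had its smallest p-values. The monocyte median was log2 -0.15 (camera adjusted p = 0.00412, adjusted p = 0.843 with an estimated correlation). Nr4a1 (log2 -0.34 ± 0.13), Cx3cr1 (log2 -0.26 ± 0.13) and Lyz2 (log2 -0.13 ± 0.066) led it. The interferon median was log2 -0.06 (camera adjusted p = 0.0101, adjusted p = 0.843 with an estimated correlation). Ifi27 (log2 -0.29 ± 0.068), Oas1a (log2 -0.32 ± 0.12) and Rtp4 (log2 -0.28 ± 0.11) led it. The erythroid median was log2 -0.09 (camera adjusted p = 0.00412, adjusted p = 0.843 with an estimated correlation). Beta globin, Hbb (log2 -0.93 ± 0.41), Ahsp (log2 -0.22 ± 0.10) and Gypc (log2 -0.17 ± 0.080) led it. Air 55 alone had Hbb at 18853 CPM, where the other air libraries had 2697 to 4420 and silica 2404 to 3489 CPM. Adjusted over the list alone, 1 interferon-stimulated gene was lower and 0 members of the other 3 lists passed.

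S100a8 was 761 ± 59.4 CPM in air and 846 ± 156 CPM in silica blood at 6 months (SD, n = 6 each; log2 0.15 ± 0.10, adjusted p = 0.671). S100a9 (log2 0.26 ± 0.11, adjusted p = 0.548), Csf3r (log2 0.26 ± 0.12), Alas2 (log2 -0.04 ± 0.093) and Isg15 (log2 -0.04 ± 0.11) did not pass. Lymphocyte genes Cd3e (log2 0.07 ± 0.067) and Ms4a1 (log2 -0.0044 ± 0.13) did not either. Of 11629 genes 1 passed edgeR's test, Phf3, a regulator of transcription by RNA polymerase II (log2 0.38 ± 0.052, adjusted p = 0.0214), a call lost with 1 surrogate variable (adjusted p = 0.136). An unadjusted p under 0.05 was reached by 1012 genes, DESeq2 called 4 and limma-voom 1. The next smallest p-values belonged to the cytokine receptor subunit Csf2rb (log2 0.40 ± 0.083, adjusted p = 0.539), RGD1307100 (log2 0.34 ± 0.076), Ikbip (log2 -0.57 ± 0.13) and the AP-1 member Fosl2 (log2 0.46 ± 0.11). Phf3 passed without air 53 and was lost without each of the other 11 libraries, with adjusted p from 0.0509 to 0.0968 and 0 genes left.

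The 4 list calls in blood at 6 months became 2 without silica 59, 2 without silica 63, 8 without silica 60 and 7 without silica 61. The neutrophil call was lost without air 51 (adjusted p = 0.0615) or 53 (0.0595) or silica 59 (0.127) or 63 (0.0882). The interferon call was lost without air 54 (adjusted p = 0.339) or 56 (0.0557) or silica 62 (0.164). The monocyte call was lost without silica 59 (adjusted p = 0.0922), and the erythroid call without silica 62 (0.0681) or 63 (0.166).

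Neutrophil, inflammasome, interferon-stimulated and immediate-early lists had a lower silica effect in blood at 6 months than at 1 day. The neutrophil difference median was log2 -0.23 (camera adjusted p = 8.02e-08, adjusted p = 0.279 with an estimated correlation). The inflammasome difference median was log2 -0.26 (camera adjusted p = 0.00620, adjusted p = 0.279 with an estimated correlation). The interferon difference median was log2 -0.24 (camera adjusted p = 8.02e-08, adjusted p = 0.563 with an estimated correlation). The immediate-early difference median was log2 -0.19 (camera adjusted p = 0.0218, adjusted p = 0.455 with an estimated correlation). Adjusted over the list alone, 3 of 20 neutrophil markers and 0 members of the other 3 lists were lower. S100a9 was at 2206 CPM at 1 day and 2263 CPM at 6 months in silica blood, and at 1295 and 1886 CPM in air blood. S100a8 was at 899 and 846 CPM in silica and 530 and 761 CPM in air blood. Isg15 was at 93.1 and 95.5 CPM in silica and 66.9 and 98.1 CPM in air blood. Csf3r was higher at 6 months in both, at 339 and 450 CPM in silica and 273 and 377 CPM in air blood. The differences for these genes thus also depend on the air groups, which were not compared between times. Of 12444 genes edgeR called 0, while 1326 had an unadjusted p under 0.05, DESeq2 called 89 and limma-voom 0. Without 1 day silica 43, 1 day silica 45 or 6 months silica 59 edgeR called 2, 1 and 3 genes, and without 6 months silica 63 there were 7 list calls. The immediate-early call was lost without 1 day silica 43 (adjusted p = 0.0867), 6 months air 52 (0.0767), or 6 months silica 58 (0.0583) or 60 (0.0539). Between the 11601 genes tested at both times, 0 edgeR calls were shared (0.0125 higher expected).

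**Figure D4:**
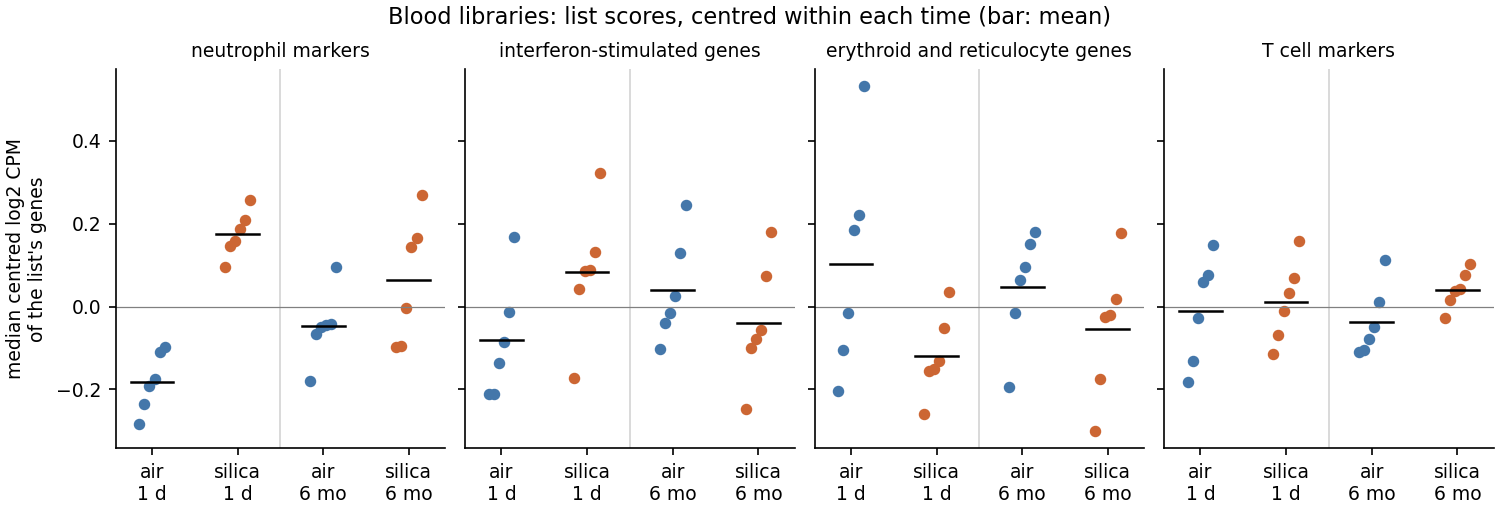
Median centred log2 CPM of the neutrophil, interferon-stimulated, erythroid and T cell lists in each blood library (6 per group), by time and treatment, with each point 1 library and the bar the group mean. At 1 day the neutrophil scores of all 6 silica libraries lie above those of all 6 air libraries.

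Silica effects were then compared between lung and blood, as blood minus lung. At 1 day, 50 genes were higher in both tissues among 11728 tested in both, where independent lists would share 12.8 (one-sided Fisher's exact p = 3.76e-18). By edgeR 0 were lower in both (1.03 expected) and 10 were called with opposite signs. The 2 tissues are taken to share animals and genes are not independent of each other, so the expected numbers and p are only a guide. Chi3l1 rose less in blood (log2 1.58 in lung and 0.44 in blood, difference -1.09 ± 0.12, adjusted p = 4.62e-06), and so did Il1r2 (log2 2.44 in lung and 0.63 in blood, difference -1.73 ± 0.28, adjusted p = 5.36e-04). The hemoglobin-binding protein gene Hp (log2 1.02 in lung and 0.43 in blood, difference -0.54 ± 0.11, adjusted p = 0.00402) and S100a9 (log2 1.87 in lung and 0.77 in blood, difference -1.06 ± 0.26, adjusted p = 0.0200) did too. The lactate transporter Slc16a3 (log2 0.84 in lung and 0.38 in blood, difference -0.40 ± 0.10, adjusted p = 0.0228) and the niacin receptor Niacr1 (log2 1.14 in lung and 0.52 in blood, difference -0.57 ± 0.16, adjusted p = 0.0450) were the last of the 6. The Niacr1 call was lost with limma-voom (adjusted p = 0.0856). Fcar (difference -0.71, adjusted p = 0.0924), Mybph (difference -0.55, adjusted p = 0.133), the leukotriene pathway gene Alox5ap (difference 0.11, adjusted p = 0.569) and Dgat2, which makes triglycerides (difference -0.04, adjusted p = 0.952), did not pass the test of a difference.

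Chemokines had a lower effect in blood at 1 day, with 4 of 21 called (5 adjusted over the list alone). The chemokine difference median was log2 -0.89 (camera adjusted p = 1.25e-06, adjusted p = 0.0214 with an estimated correlation). Proliferation genes did as well, with 16 of 28 called (22 adjusted over the list alone). The proliferation difference median was log2 -1.09 (camera adjusted p = 4.51e-36, adjusted p = 0.00510 with an estimated correlation). NF-kB genes tested lower with 2 of 20 called, also 2 adjusted over the list alone, though their median was -0.17 and their mean 0.04. That call had a camera adjusted p = 0.00441 and adjusted p = 0.369 with an estimated correlation. Enough counts in 1 tissue let a gene enter this test, and 11728 genes were tested in both tissues. Of 15989 genes 645 differed between tissues, 317 more positive and 328 more negative in blood. With the animal as a block the count was 399, the Slc16a3 call was lost (adjusted p = 0.0776) and 4 lists were called in place of 3. The count was 415 without animal 48, and 5 lists were called without animal 47 or without 48. S100a9 was lost without animal 37 (adjusted p = 0.0565), 44 (0.0597) or 47 (0.0513). Slc16a3 was lost without 8 of the 12 animals (adjusted p 0.0503 to 0.0656) and Niacr1 without 9 (0.0583 to 0.117).

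At 6 months macrophage and proliferation genes had lower silica effects in blood than in lung. Some members of the lists below had few counts in blood, among them Ccl2 at 1.31 CPM in air and in silica. Macrophage genes were more negative in 8 of 24 members (13 adjusted over the list alone). The macrophage difference median was log2 -0.61 (camera adjusted p = 2.89e-19, adjusted p = 0.00757 with an estimated correlation). Proliferation genes were in 9 of 28 (22 adjusted over the list alone). The proliferation difference median was log2 -0.72 (camera adjusted p = 1.03e-18, adjusted p = 0.0175 with an estimated correlation). Chemokine (median log2 -1.0, camera adjusted p = 4.64e-06, adjusted p = 0.0980 with an estimated correlation), complement (median log2 -0.57, camera adjusted p = 2.53e-06, adjusted p = 0.0535 with an estimated correlation) and NRF2 lists (median log2 -0.20, camera adjusted p = 1.78e-08, adjusted p = 0.0535 with an estimated correlation) also tested lower. Alveolar type 2 (median log2 -0.52, camera adjusted p = 2.53e-06, adjusted p = 0.0980 with an estimated correlation) and MHC class II lists did too (median log2 -0.37, camera adjusted p = 1.66e-05, adjusted p = 0.120 with an estimated correlation). NK (median log2 0.32, camera adjusted p = 9.53e-04, adjusted p = 0.501 with an estimated correlation) and endothelial lists (median log2 0.15, camera adjusted p = 0.0123, adjusted p = 0.347 with an estimated correlation) tested higher. Adjusted over the list alone, 7 chemokine, 4 complement, 7 NRF2, 7 alveolar type 2 and 7 MHC class II members were lower and 4 endothelial members higher.

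In the same comparison the neutrophil (median log2 -0.0076, camera adjusted p = 0.00551, adjusted p = 0.411 with an estimated correlation) and monocyte lists (median log2 -0.21, camera adjusted p = 0.0329, adjusted p = 0.450 with an estimated correlation) tested lower. The immediate-early (median log2 0.19, camera adjusted p = 0.00940, adjusted p = 0.539 with an estimated correlation) and clock lists (median log2 0.23, camera adjusted p = 0.0492, adjusted p = 0.0980 with an estimated correlation) tested higher. With the animal as a block these 4 calls were lost, at adjusted p = 0.0660, 0.345, 0.294 and 0.0693, and the neutrophil median turned to 0.0055. Enough counts in 1 tissue again let a gene enter the test. Of 15790 genes 557 differed, 158 more positive and 399 more negative in blood. On the 9 animals with both tissues 461 differed, and 198 with the animal as a block. The count was 338 without animal 51, 343 without 52, 313 without 53 and 349 without 58. Without animal 58 the endothelial call was lost (adjusted p = 0.0552) and without 49 the immediate-early call (0.0715). The monocyte call was lost without 49 (adjusted p = 0.0534), 51 (0.0594), 52 (0.0537), 53 (0.0788), 55 (0.0865) or 59 (0.0880). The clock call was lost without 49, 51, 52, 54, 55, 58, 60 or 62 (adjusted p 0.0552 to 0.116). Among 11224 genes tested in both tissues 0 edgeR calls were shared (0.106 higher expected).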

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

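The splits of the samples and the test on liver transcripts were set before their results were seen; list tests of the interactions, the splits list by list, and the tests on Rfxap, on the endothelial, alveolar type 1 and fibroblast lists, and on red cell RNA were chosen after the result was seen.

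Of 100 groups of values, 9 held a library far from the rest, where chance gives about 1 in 20. Air lung 42 at 1 day had a total count of 25876000 (next highest 16165000) and 19937 genes detected (next 19032). Silica blood 62 at 6 months had a globin share of 4.36% (next 3.84%). Among genes, Cxcl1 was 141 CPM in silica lung 44 and Scgb1a1 6542 CPM in silica lung 46 at 1 day, Spp1 was 14.5 CPM in air lung 38 at 1 day and 29.9 CPM in air lung 54 at 6 months, and air blood 40 at 1 day had Isg15 at 92.9 CPM and Alas2 at 33598 CPM.

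The silica effect differed between times for 217 lung genes and between tissues for 645 genes at 1 day and 557 at 6 months. In lung, median differences (6 months minus 1 day) of called lists were macrophage genes 0.35, complement genes 0.15, NRF2 genes 0.16, collagen and matrix genes 0.094 and alveolar type 2 genes 0.35. Those more negative at 6 months were inflammasome genes -0.065, ciliated cell markers -0.31, endothelial markers -0.11, proliferation genes -0.28, interferon-stimulated genes -0.10, immediate-early genes -0.24 and NF-kB genes -0.27. All 12 were lost with an estimated correlation (adjusted p 0.154 to 0.607). Of these the ciliated call was lost without 1 day air 37 (adjusted p = 0.0524) or 38 (0.128), 1 day silica 46 (0.0888), 6 months air 49 (0.266) or 6 months silica 58 (0.107) or 61 (0.0619). The interferon call was lost without 1 day air 39 (adjusted p = 0.0603), 1 day silica 44 (0.0693) or 46 (0.101), 6 months air 53 (0.0629) or 54 (0.218), or 6 months silica 61 (0.181) or 62 (0.0664). The inflammasome call was lost without 1 day air 40 (adjusted p = 0.0601) or 6 months air 51 (0.0673), air 54 (0.0708) or silica 61 (0.103), and the endothelial call without 6 months silica 58 (0.0564). In blood they were inflammasome genes -0.26, neutrophil markers -0.23, interferon-stimulated genes -0.24 and immediate-early genes -0.19 (adjusted p 0.279 to 0.563 with an estimated correlation). Between tissues (blood minus lung) at 1 day they were inflammatory chemokines -0.89, proliferation genes -1.09 and NF-kB genes -0.17. At 6 months they were inflammatory chemokines -1.0, neutrophil markers -0.0076, macrophage genes -0.61, monocyte markers -0.21, complement genes -0.57, NRF2 genes -0.20, alveolar type 2 genes -0.52, proliferation genes -0.72 and MHC class II genes -0.37, and in the other direction endothelial markers 0.15, NK markers 0.32, immediate-early genes 0.19 and clock genes 0.23. Called single genes were Tchh 1.97, Pcsk1n 1.3, Ncf1 0.99, Krt79 1.55, Fabp4 2.09, Lcn2 -1.03, Cxcl1 -1.55 and Sftpc 0.32 between lung times, and Chi3l1 -1.09, Il1r2 -1.73, Hp -0.54, S100a9 -1.06, Slc16a3 -0.40 and Niacr1 -0.57 between tissues at 1 day.

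Each count was set against 100 splits of the same libraries, the real one included. For genes, a chance assignment of single animals was argued against in lung at 1 day (2163, highest other 2, 1 of 100 as large). The same held for lung at 6 months (2484, highest other 2, 1 of 100) and blood at 1 day (168, highest other 13, 1 of 100). With 100 splits, 1 of 100 is the smallest share possible. Chambers and cage pairs are not given, so a chance difference between those stays open. Between tissues at 1 day (645, highest other 11) and 6 months (557, highest other 6) 1 of 100 was as large. Between lung times (217) 4 of 100 were as large. Splits mix the silica labels, which removes the silica effect itself. They therefore cannot exclude chance for a difference in that effect between times or tissues. The highest other split between lung times called 1448; the 3 splits above the real count kept most real labels at 1 time and few at the other, which turns the silica effect itself into a difference between times, a structure of the samples. Chance cannot be excluded for the 1 gene in blood at 6 months (9 of 100; highest other 2). Between blood times edgeR called 0 genes, which every split reaches (100 of 100; highest other 6), so the splits decide nothing there. Chance cannot be excluded for any count of lists with the preset correlation: lung at 1 day 14 (17 of 100; highest other 18), lung at 6 months 14 (31; 20), blood at 1 day 7 (57; 13), blood at 6 months 4 (70; 14), lung times 12 (28; 21), blood times 4 (81; 14), tissues at 1 day 3 (67; 12) and at 6 months 13 (7; 15).

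List by list, a check made because other splits reached the counts of lists, and with no correction over lists, fewer than 5 of the 100 splits gave as small a p for 7 of 14 called lists in lung at 1 day (chemokines, inflammasome, complement, alveolar type 1 and proliferation 1 each, neutrophil 2, NF-kB 4), but endothelial was matched in 7 and fibroblast in 26. In lung at 6 months this held for 8 of 14 (chemokines, neutrophil, macrophage, complement, NRF2, alveolar type 2, endothelial and proliferation, 1 each), with fibroblast matched in 9 and alveolar type 1 in 28. In blood at 1 day it held for 3 of 7 (inflammasome 1, neutrophil 1, immediate-early 3). In blood at 6 months it held for 0 of 4, where 11 to 40 splits gave as small a p. Between lung times it held for 3 of 12 (macrophage 1, NRF2 1, alveolar type 2 2) and between blood times for 2 of 4 (inflammasome 2, neutrophil 2). Between tissues it held for 2 of 3 at 1 day (chemokines, proliferation) and 6 of 13 at 6 months (chemokines, macrophage, complement, NRF2, alveolar type 2, proliferation). As with the gene counts, the splits remove the silica effect itself. For lists that differed between times or tissues they therefore cannot exclude chance, and no conclusion was drawn there.

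Rfxap was estimated at 0 in 6 of 6 silica lungs at 1 day, and at 6 months in 5 of 6 silica and 2 of 5 air lungs. The sum of the gene models of that name changed by -0.019 (SE 0.060) on the log2 scale. That argues against a lower Rfxap transcript level with silica (adjusted p of the sum = 0.882) and is consistent with reads moving between gene models of one name. Single reads were not examined, and why the estimate was 0 in nearly all silica lungs stays open.

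The endothelial, alveolar type 1 and fibroblast lists tested lower in silica lung at both times; with an estimated correlation only the alveolar type 1 call at 1 day held (the others adjusted p 0.0772 to 0.488). Normalization shifted by the genes that rose, with no other change, would lower alveolar type 2 genes alike. So would resident lung RNA diluted by added cells that lack these transcripts. Yet alveolar type 2 genes lay above the 3 lists by 0.266 at 1 day (exact permutation p = 0.0216) and 0.676 at 6 months (exact permutation p = 0.00216). Blood held some of these transcripts. In air blood at 1 day Napsa was at 167 CPM (442 in air lung), Abca3 at 29.6 (578) and Lpcat1 at 22.0 (464). Added cells that express these genes, and a change in alveolar type 2 cells, stay open. Ciliated and club lists differed from the 3 lists by 0.168 at 1 day (exact permutation p = 0.184) and 0.000165 at 6 months (exact permutation p = 0.998). Resident lung RNA diluted by added cells, together with other changes, and lower expression in those cells with silica therefore cannot be told apart, since neither of these 2 differences exceeded what permuted labels gave, and both may contribute. Normalization together with other changes stays open as well.

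The neutrophil list was higher in silica blood at 1 day. Less red cell RNA would raise T and B cell lists alike, but the neutrophil list rose above these by 0.346 (exact permutation p = 0.0022, the smallest that 924 permutations can give). Liver transcripts in 4 libraries are argued against, since the list median without them was 0.40 (camera adjusted p = 1.18e-30). A larger neutrophil share and changes in neutrophils or in other cells expressing these genes may each contribute, as hypotheses, and bulk values of these libraries did not part them.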

How the results depend on the processing

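The robust dispersion estimates, summed gene models, list tests of the interactions and the fit without 4 blood libraries were chosen after the data were seen; all other alternatives were planned. A test against a 1.5-fold change left 157 genes in lung at 1 day, 77 in lung at 6 months and 0 in blood at either time, by construction fewer. DESeq2 called 353 genes in blood at 1 day, 4 in blood at 6 months, 346 between lung times and 89 between blood times, and 1 surrogate variable gave 271 in blood at 1 day and 0 at 6 months; the cause was not tested. With the replicate block, on animals with both tissues, 399 genes differed between tissues at 1 day and 198 at 6 months (fewer animals at 6 months), and beyond the calls given with those results it changed no other call of a named gene or list. Without the 4 blood libraries with liver transcripts 74 genes were called in blood at 1 day, on fewer samples, and the platelet median turned to 0.025 (adjusted p = 0.529); the cause was not tested. With an estimated correlation 7 lists were called in lung at 1 day, 0 in lung at 6 months, 3 in blood at 1 day, 0 in blood at 6 months, 0 between lung times, 0 between blood times and 2 between tissues at 6 months. By contrast fry called 3 in blood at 1 day, 0 in blood at 6 months, 5 between lung times, 0 between blood times and 8 between tissues at 6 months. At a threshold of 0.01 the lung times shared 364 higher, 81 lower and 8 opposite calls, and lung and blood at 1 day 7 higher and 0 opposite. With DESeq2 the latter shared 90 higher, 4 lower and 24 opposite, and lung and blood at 6 months 1 higher. Leaving out 1 library at a time gave 1754 to 2099 genes and 12 to 16 lists in lung at 1 day, 1863 to 2610 and 12 to 15 in lung at 6 months, 86 to 211 and 5 to 7 in blood at 1 day, 0 to 1 and 2 to 8 in blood at 6 months, 149 to 254 and 9 to 14 between lung times, 0 to 3 and 3 to 7 between blood times, 415 to 650 and 3 to 5 between tissues at 1 day, and 313 to 609 and 10 to 15 at 6 months. Counts under all other alternatives lay within 1.5 times those reported. The 1.5-fold test lost 88 named calls and the fit without the 4 libraries 12; other settings that leave out no library lost 11 in blood at 1 day, 11 in lung at 6 months, 7 in lung at 1 day, 2 between tissues at 1 day and 1 in blood at 6 months. With these depths a simulated 1.5-fold change was recovered for 76% of genes at 1 day and 64% at 6 months. As a difference it was recovered for 48% between lung times and 54% between blood times. Between tissues that was 44% at 1 day and 46% at 6 months. The smallest simulated change, below 1.5-fold, was recovered for 48% in lung and 24% in blood at either time. As a difference that was 30% between lung times, 10% between blood times, and 14% and 12% between tissues. Smaller effects were thus partly out of reach in lung, and mostly in blood and as differences. The simulated data held 200 changed genes, whereas 1 gene was called in blood at 6 months, so the rates may not hold there.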

Other observations

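No test in this part was used to choose a list; single genes named here were chosen after their values were seen. Matrix and airway genes moved one by one in lung without their lists passing. Of 26 collagen and matrix genes at 1 day, 4 rose, among them Cthrc1 0.65, and 4 fell, such as elastin, Eln -0.28 (median -0.03, mean 0.04, camera adjusted p = 0.872, 6 and 4 adjusted over the list alone). At 6 months 4 rose, among them Cthrc1 0.68, Mmp14 0.52 and Tnc 0.36, and 0 fell (median 0.08, mean 0.16, camera adjusted p = 0.0849; likewise adjusted over the list alone). Of club and goblet markers, Bpifb1 (2.77-fold) and Pigr 0.58, the receptor that carries IgA into the airway, rose at 1 day (median -2.5e-04, mean 0.19, camera adjusted p = 0.107), and Bpifb1 3.13, Pigr 0.66 and Spdef 0.45 at 6 months (median -0.24, mean 0.08, camera adjusted p = 0.166). At 1 day 3 of 13 were higher and 1 lower, and at 6 months 4 of 12 and 1, the same counts adjusted over the list alone. The ciliated list at 1 day (median -0.03, mean -0.05, camera adjusted p = 0.237) had 1 of 11 lower. The alveolar type 2 list at 1 day (median 0.13, mean 0.10, camera adjusted p = 0.110) had 2 of 14 higher and 2 lower, and NRF2 genes at 1 day moved both ways (8 of 22 higher, 9 lower; median -0.04, mean 0.19, camera adjusted p = 0.200), with Mt2A 1.67 and Slc7a11 1.12 higher and Gsta1 -0.35 lower.

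Median and mean had opposite signs for the collagen, NRF2, club, monocyte, mast cell and clock lists in lung at 1 day, and for the club and T cell lists at 6 months. At 6 months inflammasome (median 0.14, mean 0.21, camera adjusted p = 0.0876), interferon-stimulated (median 0.02, mean 0.05, camera adjusted p = 0.865), erythroid (median -0.33, mean -0.21, camera adjusted p = 0.160) and NF-kB lists (median 0.15, mean 0.16, camera adjusted p = 0.201) did not pass in lung either, nor did immediate-early genes at 1 day (median 0.12, mean 0.21, camera adjusted p = 0.507). In blood 5 lists had fewer than 5 tested genes.

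T and B cell lists did not pass in lung. At 1 day T cell (median 0.02, mean 0.01, camera adjusted p = 0.723), B cell (median 0.06, mean 0.10, camera adjusted p = 0.354), monocyte (median 0.10, mean -0.02, camera adjusted p = 0.872), mast cell and granulocyte (median 0.02, mean -0.07, camera adjusted p = 0.872), platelet (median -0.15, mean -0.02, camera adjusted p = 0.872) and adipose, muscle and mesothelial lists (median -0.30, mean -0.33, camera adjusted p = 0.141) were not called. At 6 months T cell (median -0.04, mean 0.02, camera adjusted p = 0.771), B cell (median -0.08, mean -0.08, camera adjusted p = 0.559) and monocyte lists (median 0.10, mean 0.10, camera adjusted p = 0.339) were not called. Mast cell (median 0.16, mean 0.42, camera adjusted p = 0.632), platelet (median -0.17, mean -0.15, camera adjusted p = 0.529) and adipose lists (median -0.41, mean -0.36, camera adjusted p = 0.865) were not called either. Single members did move at 6 months, with the mast cell protease Cpa3 1.53 and the costimulator Icos 0.65 higher and Cd8a -0.44 and F13a1 -0.64 lower. In blood at 1 day T cell (median 0.02, mean 0.02, camera adjusted p = 0.614) and B cell lists (median -0.02, mean -0.03, camera adjusted p = 0.715) were not called, nor were proliferation genes (median -0.06, mean -0.03, camera adjusted p = 0.715) with 0 of 28 members past edgeR's threshold.

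Clock genes differed in silica lung at 1 day: Nr1d1 1.71, Dbp 0.96, Per3 0.85 and Nr1d2 0.85 were higher, and Arntl -0.47 and Cry1 -0.70, of the opposite phase, lower. With members going both ways, 5 of 16 higher and 4 lower (5 and 5 adjusted over the list alone), the list was not called (median -0.04, mean 0.15, camera adjusted p = 0.872). At 6 months Bhlhe41 0.82 was higher and Arntl -0.21 and Cry2 -0.24 lower (median -0.14, mean -0.04, camera adjusted p = 0.166). The time of killing is not given in the sources used here, so these values were not tied to treatment or to hour, and no explanation was tested.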
